A study of Homo sapiens with 11 samples.

How the data were processed

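Gene expression was measured on 11 microarrays of total RNA from 7 established prostate cancer cell lines. RNA was extracted with a Qiagen RNeasy kit and DNase treatment, and the labelling was run as a service by Thermo Fisher, per the labels' protocols. DU145, VCaP, MDAPCa2a and MDAPCa2b had 2 arrays each, from consecutive passages of the culture, and LNCaP, 22RV1 and PC3 had 1 array each. Nothing in the labels says that the 2 passages of a line came from separate thaws, so the p-values measure only the spread between consecutive passages. The labels hold no batch, slide or scan information, and media differed between lines: MDAPCa2a and MDAPCa2b alone grew in HPC1 medium on a coated surface.

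The values are log2 expression levels as deposited by the authors in 1 table for all arrays. Per the submitters' processing notes, they came from RMA in the Transcriptome Analysis Console. The versions of these tools and the annotation build are not given in the sources used here. RMA corrects background, brings all arrays to the same distribution and combines the probes of a feature, so a change shared by all genes cannot be seen in these values. The values ran from 1.80 to 18.91. They exceeded 16, the log2 of the largest value of a 16-bit scanner, so the scale was changed by a step that no source names. Whether that step stretched or shifted the scale was not tested. Differences and folds are on the deposited scale and are not calibrated to RNA.

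The table held 24351 features. A table of probe names paired 17709 of them with exactly 1 gene and 0 with several; all 17709 were matched by gene ID to a current gene table and 0 symbols needed an update. A further 3739 features had no gene name here and were left out of the tests, as were 612 negative controls, 2197 positive controls, 31 AFFX controls and 63 ERCC spike-ins. For the 20 genes with more than 1 feature, the one with the highest mean over all arrays was used, which left 17687 genes. Some genes of the lists named below are not reported here.

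Arrays have no read depth, and their small number limits the precision. Signal over background was judged from the negative controls. On each array, their 95th percentile was taken as the background line. A gene was in the background range of a line when it lay below that line on all of the arrays concerned. Where the dimmer side of a comparison was in the background range, the difference is given as a lower bound ("at least"): the mean of the brighter side minus the mean, over the arrays of the dimmer side, of the background line or the gene's own value, whichever was higher. Adjusted p-values of such genes come from the fit on the measured values. For a few named genes only some arrays or lines of the dimmer side were below that line, and where this moved the size by more than 0.1 log2 units the same bound is printed. No size is given where both sides were in the background range or the bound was not above 0.

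Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes). For pairs of lines, 1 model with a coefficient for each of the 7 lines was fitted to all 11 arrays. The 4 replicated lines gave 1 shared estimate of the spread with 4 residual degrees of freedom, and the single PC3 array was assumed to vary like them. A gene was called when its Benjamini-Hochberg adjusted p over all 17687 genes was under 0.05 and its log2 difference was at least 1 in size. Differences among all lines were tested with the moderated F test, with a range of line means of at least 1. For the comparison of bone-derived lines (PC3, VCaP, MDAPCa2a, MDAPCa2b) with the others (LNCaP, 22RV1, DU145), the line was the replicate and 1 mean per line entered the fit. 22RV1, whose label names an adenocarcinoma and growth in mouse bone, was kept with the others. 22RV1 and LNCaP were compared without a test.

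Gene lists were androgen-responsive genes, luminal and basal epithelium, mesenchymal genes, neuroendocrine genes, osteoblast-type genes, secreted factors that promote bone formation and bone resorption, ETS family drivers, tumour suppressors, cell cycle, interferon response, antigen presentation by MHC class I, nuclear architecture and chromosome folding, sterol and steroid metabolism, hypoxia and glycolysis, and glucocorticoid-responsive genes. Markers of immune, endothelial and fibroblast cells stood for other cells a culture could hold. A few genes are in more than 1 list, among them ERG, SPARC, NDRG1 and VEGFA. The list of resorption factors is broad and also holds DKK1, an inhibitor of bone formation, and JAG1, a Notch ligand. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 20 lists of a comparison, with an estimated correlation and with fry as alternatives. Called members were counted over all genes and with p-values adjusted over the list alone. For 22RV1 against LNCaP, a list's median was placed among 10000 random lists of the same size matched on mean level.

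Genes named in the text were, for each tested comparison, the 6 with the highest and the 6 with the lowest difference among called genes whose arrays (line means for the bone comparison) did not overlap, filled up by the smallest p where fewer were called. The rule also took up to 2 called members from each end of every list with at least 2 called members, and for the pair without a test the 6 largest differences in each direction and list members among the 100 largest. Y-linked genes, XIST and genes without a plain symbol were not named. KLK3, ERG, ETV1, CDH1, VIM, RUNX2 and ZEB1 were named in every line. Where a list had only 1 called member it was named too, a choice made after its value was seen. The groups, tests, lists, naming rule and all alternatives except the leave-outs of gene lists were fixed before the data were examined.

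The order of genes along chromosomes came from a gene table of assembly GRCh38.p14. The authors' build is not given, so this table served only for which genes neighbour each other. The correlation of log2 differences between adjacent genes was compared with 10000 shuffles of gene positions (one-sided permutation test).

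The steps were tested on simulated data with the measured mean levels of all 17687 genes, their spread as moderated by limma and 200 changed genes. Far more genes were called in the measured data, 5175 for VCaP against PC3 and 5596 for VCaP against DU145. The adjustment of p-values depends on how many genes change, so the simulated shares and false calls need not hold for these 2 comparisons. In VCaP against PC3, 11.9% of genes changed by 1 log2 unit, 98.5% of those changed by 2 and 100% of those changed by 4 were called, with 9 false among 149 calls. The shares were 29.9%, 100% and 100% in VCaP against DU145 (7 false among 160) and 37.3%, 95.5% and 100% in MDAPCa2b against MDAPCa2a (12 false among 167). The bone comparison called only 1.49%, 46.3% and 75.8% (2 false among 84). Camera, simulated for VCaP against DU145, found the shifted list in 20 of 20 draws and called 0 of 380 unshifted lists. The simulated genes varied independently, unlike those of some real lists (estimated correlation 0.468 for cell cycle genes in that comparison). The simulation therefore does not show how often camera at the preset correlation calls such lists wrongly.

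Alternatives were other scalings between arrays, a filter on dim genes, all features or the mean of a gene's features, a trended and robust variance prior, no or a stricter fold minimum, fits on fewer arrays, each array or line left out in turn, other places of 22RV1, the MDAPCa lines averaged, and the line as a random block.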

Results

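Gene expression was measured in 7 prostate cancer lines that the series places along a range from adenocarcinoma to bone metastasis. LNCaP came from a lymph node metastasis, DU145 from a brain metastasis, and PC3, VCaP, MDAPCa2a and MDAPCa2b from bone metastases, of which PC3 is described as osteoclastic (bone-resorbing) and VCaP as osteoblastic (bone-forming). 22RV1 is described as an adenocarcinoma that spread to bone in mice. Between 8113 genes (MDAPCa2b replicate 1) and 9828 genes (DU145 replicate 2) lay above the background line of an array, 45.9% to 55.6% of the 17687 genes. In all, 6468 genes were in the background range on every array. The area under the curve that separates positive from negative controls lay between 0.977 and 0.985.

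The 2 passages of a line differed by a standard deviation of 0.22 (MDAPCa2a), 0.31 (VCaP), 0.32 (DU145) and 0.36 (MDAPCa2b) log2 units over genes. Across genes, which are not independent replicates, the correlation between passages was 0.995 in MDAPCa2a, 0.991 in VCaP, 0.991 in DU145 and 0.988 in MDAPCa2b. MDAPCa2b had 880 genes at least 1 log2 unit apart between its passages, against 106 in MDAPCa2a. Between line means, the highest correlation was that of MDAPCa2a with MDAPCa2b (0.990) and the lowest that of DU145 with VCaP (0.869). DU145 and PC3 (0.921) clustered together, apart from the other 5 lines, among which LNCaP lay close to MDAPCa2b (0.948). In the moderated F test of limma, 10209 genes (57.7%) differed among the lines. Of all 17687 genes, called or not, 2065 (11.7%) had line means spread over at least 4 log2 units.

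**Figure D1:**
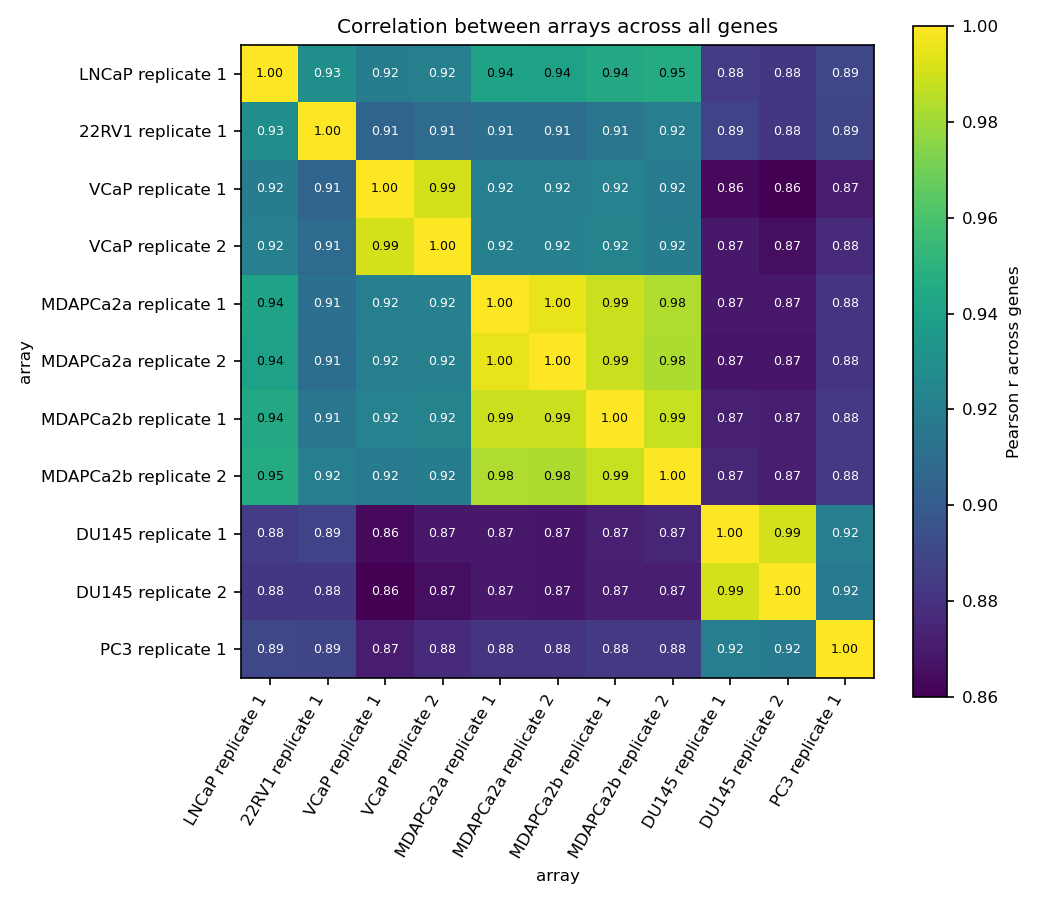
Pearson correlation across all 17687 genes between each pair of the 11 arrays, from dark (low) to bright (high). Arrays of 1 line form bright squares, MDAPCa2a and MDAPCa2b share a bright square, and DU145 and PC3 stand apart from the other 5 lines, with 0.8598 between DU145 replicate 2 and VCaP replicate 1 as the lowest value.

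Markers of prostate and cell state separated the lines. KLK3, the gene of prostate-specific antigen, reached 17.34 ± 0.02 (SD, n = 2) in MDAPCa2a, 16.94 ± 0.15 (SD, n = 2) in MDAPCa2b and 15.91 in LNCaP (1 array). Its level was 9.77 ± 0.01 (SD, n = 2) in VCaP, 7.95 in 22RV1, 6.62 in PC3 and 6.53 in DU145. ERG, an ETS transcription factor often fused in prostate cancer, was 16.24 ± 0.22 (SD, n = 2) in VCaP and in the background range in all other lines. ETV1, another ETS factor, was 16.39 ± 0.15 in MDAPCa2b and 16.24 ± 0.05 in MDAPCa2a (SD, n = 2 each), 14.60 in LNCaP, 11.76 in PC3 and 10.55 in 22RV1, and in the background range in VCaP and DU145. VIM, the intermediate filament of mesenchymal cells, and ZEB1, a repressor of epithelial genes, were above background only in DU145 (13.63 ± 0.10 and 10.46 ± 0.03, SD, n = 2) and PC3 (13.67 and 10.51). CDH1, the epithelial cadherin, was lowest in PC3 (8.11) and DU145 (10.65 ± 0.93, SD, n = 2) and lay between 12.53 and 13.88 elsewhere. RUNX2, a transcription factor of bone-forming cells, rose above the background line only in PC3 (6.77).

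**Figure D2:**
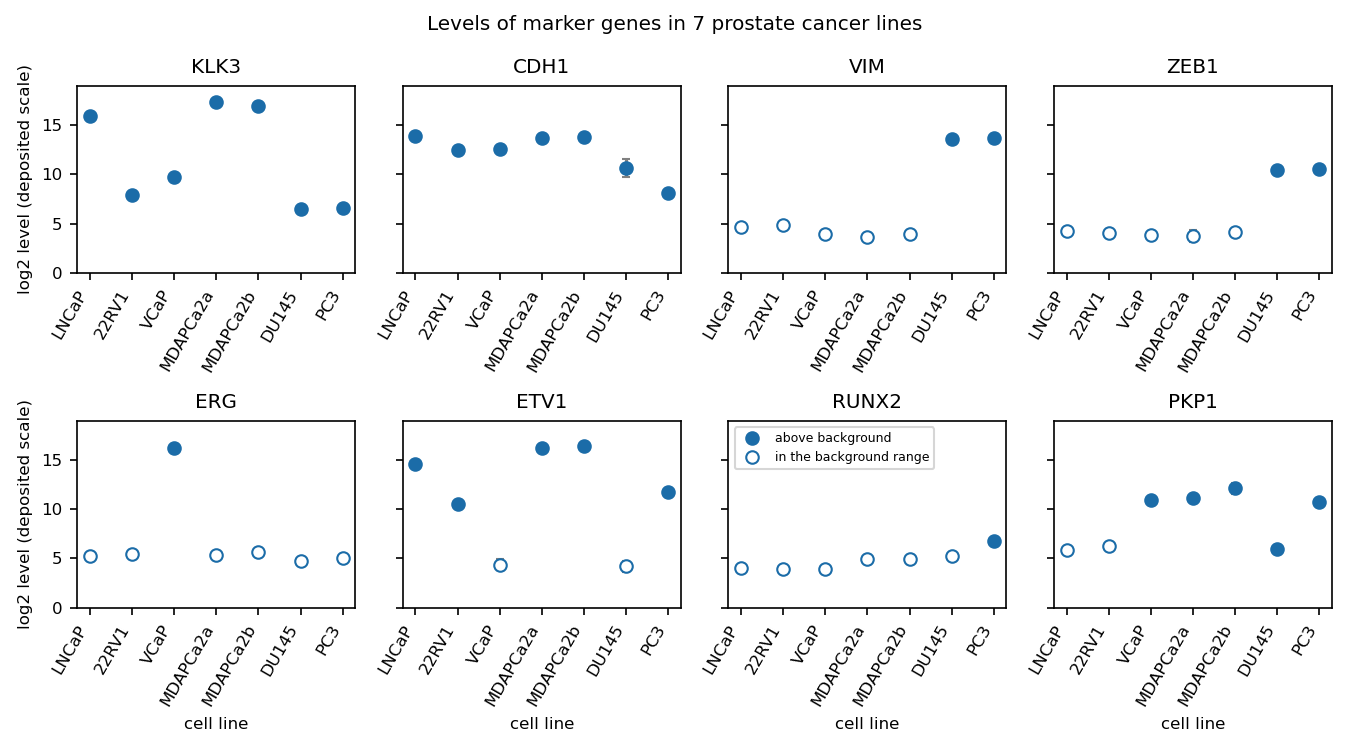
Deposited log2 level (vertical axis) of 8 marker genes in the 7 lines (horizontal axis). Points are means of 2 arrays with the SD as a bar (VCaP, MDAPCa2a, MDAPCa2b, DU145) or single arrays, and open points are in the background range. ERG stands out in VCaP at 16.24, VIM is filled only in DU145 (13.63) and PC3 (13.67), and PKP1 lies between 10.73 and 12.12 in the 4 bone-derived lines.

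VCaP, the osteoblastic line, was set against PC3, the osteoclastic line. Each kind is represented by a single line, so its effect cannot be separated from other differences between these lines. The genes furthest above PC3 in VCaP included secreted proteins of prostate epithelium. ACP3, prostatic acid phosphatase, was at least 10.78 log2 units higher in VCaP, KLK2, a protease of prostate fluid, at least 8.93, NPY, a neuropeptide, at least 9.02, APOD, an apolipoprotein, at least 9.28, CRISP3 at least 8.77 and ERG at least 9.76. In PC3, DKK1, a secreted inhibitor of Wnt signalling and of bone formation, was at least 10.31 log2 units higher, and MSMP, a microseminoprotein, at least 10.67. FOSL1, a subunit of the AP-1 transcription factor, was at least 9.40 units higher in PC3, APOBEC3C, a cytidine deaminase, 9.89, LGALS1, a galectin, 8.33 and TIMP1, an inhibitor of metalloproteinases, 7.62. These 12 differences had limma adjusted p-values from 9.77e-09 to 1.09e-07, with an SE of the fitted difference of 0.27 to 0.44 (VCaP n = 2, PC3 n = 1).

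Of 17687 genes, 5175 (29.3%) were called between VCaP and PC3, 2497 higher and 2678 lower in VCaP, and 661 were at least 4 log2 units apart. On the lower side, 1457 of the called genes were in the background range, and for a further 594 both sides were. Without VCaP replicate 1 the count was 4703 and without replicate 2 it was 4915. The 20 gene lists were tested with camera and 10 passed; 3 of them also passed with an estimated correlation (androgen-responsive, mesenchymal and interferon response genes).

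Androgen-responsive genes were higher in VCaP than in PC3 for 17 of 22 measured members, lower for 2 and not called for 3 (19 called when adjusted over the list alone). The median difference was 3.52 log2 units, with the same value when genes in the background range were set at their bounds (camera adjusted p = 4.02e-10; adjusted p = 0.0188 with an estimated correlation). Beside ACP3 and KLK2, the members at the ends of the list were ALDH1A3, a retinaldehyde dehydrogenase, 6.54 ± 0.26 (SE) units lower in VCaP, and STEAP4, a metalloreductase, at least 1.09 units lower. Among luminal epithelium genes, 13 of 23 were higher, 1 lower and 9 not called (14 over the list alone; camera adjusted p = 6.56e-05; adjusted p = 0.191 with an estimated correlation). FOLH1, the prostate-specific membrane antigen, was at least 8.64 units higher in VCaP and STEAP1, a surface antigen of prostate, 6.37 ± 0.35 (SE), whereas KRT19, a keratin, was 5.45 ± 0.30 (SE) lower.

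Mesenchymal genes were lower in VCaP for 17 of 27 members, higher for 2 and not called for 8 (19 over the list alone), with a median difference of -3.34 and -1.81 with members at their bounds (camera adjusted p = 3.7e-08; adjusted p = 0.0188 with an estimated correlation). VIM was at least 7.15 log2 units lower in VCaP, and LOX, a collagen cross-linking enzyme, and ACTA2, a smooth muscle actin, were at least 1.20 and 1.87 units higher. Of 13 basal epithelium genes, 7 were lower, 1 higher and 5 not called (8 over the list alone; camera adjusted p = 0.0076; adjusted p = 0.255 with an estimated correlation). SFN, a 14-3-3 protein of squamous epithelium, was at least 5.98 units lower in VCaP, and ITGB4, a hemidesmosome integrin, at least 3.72, while BCAM, an adhesion molecule that binds laminin, was 5.75 ± 0.54 (SE) higher. Neuroendocrine genes were higher in VCaP for 10 of 20, lower for 3 and not called for 7 (13 over the list alone; camera adjusted p = 0.0037; adjusted p = 0.153 with an estimated correlation). CHGA, chromogranin A of secretory granules, was at least 1.83 units higher and UCHL1, a neuronal ubiquitin hydrolase, at least 3.15; the median of this list was 1.36 and 0 with members at their bounds.

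Factors that act on bone were set by list. Of 20 secreted factors that promote bone resorption, 11 were lower in VCaP, 0 higher and 9 not called (11 over the list alone; camera adjusted p = 0.000441; adjusted p = 0.0726 with an estimated correlation). The median of this list was -1.15, and -0.269 with members at their bounds, and 7 of the 20 were in the background range on all arrays. Beside DKK1, MMP13, a collagenase, was at least 2.92 log2 units lower in VCaP. Secreted factors that promote bone formation moved both ways, with 2 of 21 higher, 6 lower and 13 not called (8 over the list alone), and the list did not pass (camera adjusted p = 0.229); its median of 0.0351 and its mean of -0.937 differ in sign. TGFB1 was at least 4.54 and BMP4, a bone morphogenetic protein, at least 2.76 log2 units lower in VCaP, and BMP7, another of them, at least 1.33 higher. Osteoblast-type genes had 2 of 18 higher, 3 lower and 13 not called (5 over the list alone; camera adjusted p = 0.951), with a median of 0.161 and a mean of -0.0817. MGP, an inhibitor of calcification, was at least 4.28 units higher in VCaP and TNC, an extracellular matrix protein, at least 3.10, while CDH11, a cadherin of osteoblasts, was at least 3.71 lower and SPARC, a matrix protein of bone, at least 2.99.

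Interferon response genes were lower in VCaP for 20 of 26 members, higher for 0 and not called for 6 (21 over the list alone), with a median of -2.99 and -1.31 with members at their bounds (camera adjusted p = 6.49e-11; adjusted p = 0.0188 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, was 6.19 ± 0.41 (SE) log2 units lower in VCaP, and OAS2, an oligoadenylate synthetase, at least 2.91. Genes of antigen presentation by MHC class I were lower for 8 of 14, higher for 0 and not called for 6 (8 over the list alone; camera adjusted p = 6.56e-05; adjusted p = 0.0983 with an estimated correlation). HLA-C, a heavy chain, was at least 3.84 units lower in VCaP and B2M, the shared light chain, 1.92 ± 0.32 (SE); HLA genes are close copies of each other, so their separate levels are uncertain.

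Sterol and steroid metabolism genes were higher in VCaP for 12 of 24, lower for 0 and not called for 12 (14 over the list alone; camera adjusted p = 2.38e-05; adjusted p = 0.191 with an estimated correlation). UGT2B15, which conjugates androgens for removal, was at least 3.33 log2 units higher, although it shares sequence with its relatives, and ACACA, acetyl-CoA carboxylase, was at 14.57 in VCaP and 10.06 in PC3. Nuclear architecture genes had 14 of 43 higher, 3 lower and 26 not called (18 over the list alone; camera adjusted p = 0.0207; adjusted p = 0.433 with an estimated correlation), and the list did not pass without VCaP replicate 2 (adjusted p = 0.0922). LBR, the lamin B receptor, was 2.85 ± 0.32 (SE) units higher in VCaP and DNMT3A, a DNA methyltransferase, 2.81 ± 0.25 (SE), whereas LMNA, the gene of lamins A and C, was 5.67 ± 0.30 (SE) lower, and DNMT1, the maintenance methyltransferase, 1.48 ± 0.34 (SE).

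Other lists did not pass between VCaP and PC3 in the fit on all arrays. ETS family drivers had 1 of 6 higher (ERG) and 4 lower (5 over the list alone; camera adjusted p = 0.0952), among them ETV5 and ETV1, at least 4.80 and 5.24 log2 units lower in VCaP. Cell cycle genes had 1 of 30 higher, 7 lower and 22 not called (7 over the list alone; adjusted p = 0.116, and 0.0112 without VCaP replicate 2). Tumour suppressors had 7 of 18 higher and 1 lower (8 over the list alone; adjusted p = 0.0564, and 0.0361 without VCaP replicate 1 and 0.043 without either MDAPCa2b array). CDKN2A, an inhibitor of cyclin-dependent kinases, was at least 4.32 units lower in VCaP, and CDKN1B, another such inhibitor, 2.51 ± 0.27 (SE) higher. Hypoxia and glycolysis genes had 3 of 21 higher and 8 lower (12 over the list alone; adjusted p = 0.062, and 0.0335 without VCaP replicate 1 and 0.0307 without either MDAPCa2b array), with BNIP3L, a mitophagy receptor, at least 7.62 units lower in VCaP. Glucocorticoid-responsive genes had 4 of 13 higher and 5 lower (9 over the list alone; adjusted p = 0.932). Markers of other cells were mostly in the background range on all arrays (8 of 13 immune, 9 of 12 endothelial and 9 of 13 fibroblast genes). Among them, 1 immune, 2 endothelial and 3 fibroblast genes were called over all genes and as many when adjusted over the list alone (camera adjusted p = 0.519, 0.839 and 0.519). CD68, a lysosomal protein of macrophages that other cells also make, was at least 2.15 log2 units lower in VCaP, and the called endothelial gene higher in VCaP was ERG.

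**Figure D3:**
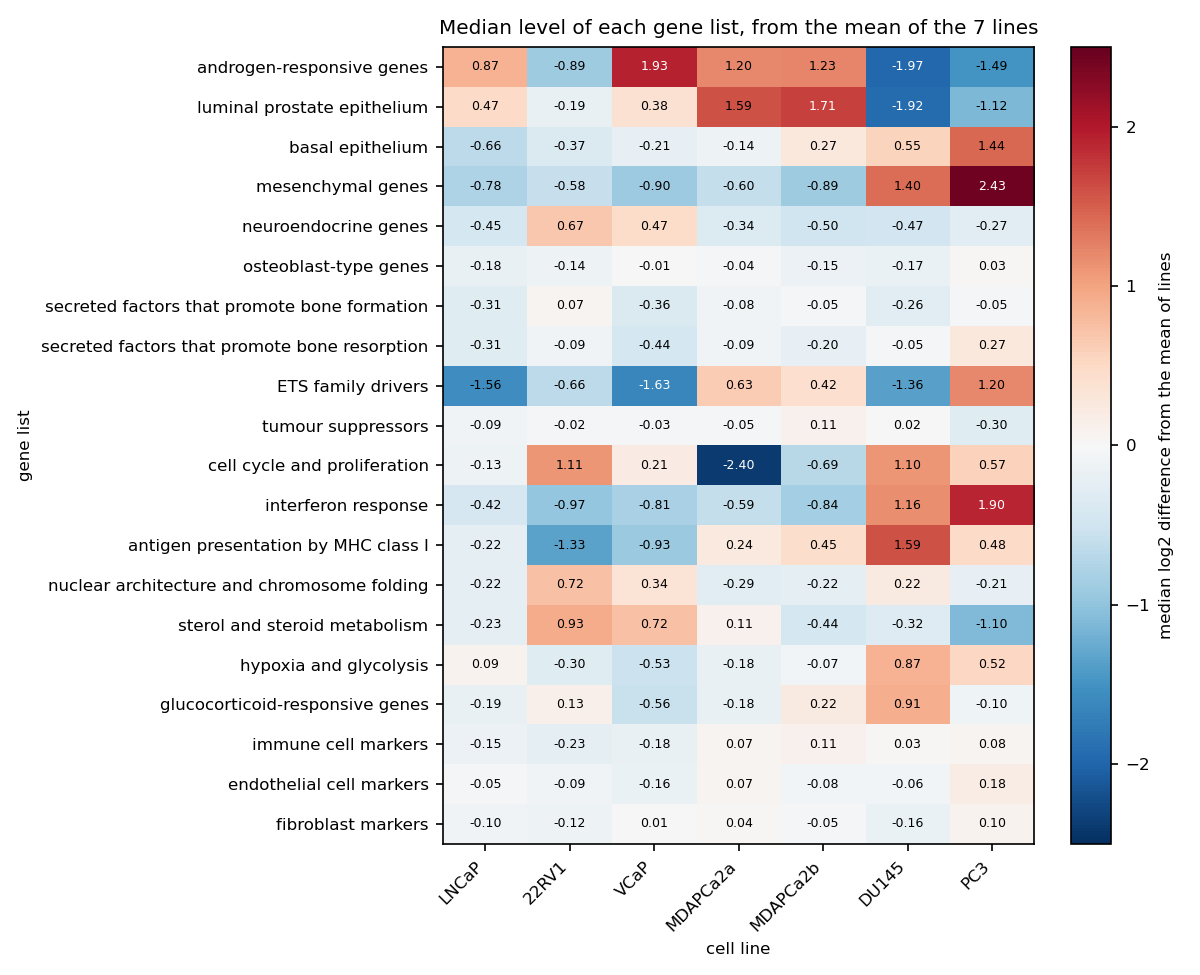
Median over the genes of each of the 20 lists (vertical axis) of the log2 level in each line (horizontal axis) minus the mean of the 7 lines, with blue for lower and red for higher. PC3 and DU145 are red for mesenchymal and interferon response genes and blue for androgen-responsive and luminal genes, and MDAPCa2a is the lowest line for cell cycle genes, with a median of -2.40.

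VCaP, from a bone metastasis, was set against DU145, a line from a brain metastasis. With a single line of each origin, differences of origin cannot be separated from other differences between these lines. PC3, also from bone, correlated more closely with DU145 (0.921) than with VCaP (0.876). ACP3 was at least 11.31 log2 units higher in VCaP, KLK2 at least 9.46, NPY 9.55, APOD 9.81, ERG 10.28 and FOLH1 9.17. In DU145, NQO1, a quinone reductase of the oxidative stress response, was at least 10.39 log2 units higher, LMO3, a transcription cofactor, 9.62, and BNIP3L 9.40. EDIL3, an extracellular matrix protein, was at least 9.01 units higher in DU145, CYP24A1, which breaks down vitamin D, 7.93 and TGFBI, a matrix protein, 7.81. These 12 genes had limma adjusted p-values from 9.43e-10 to 4.84e-09 and an SE of the fitted difference of 0.21 to 0.33 (n = 2 in each line).

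In this comparison, 5596 genes (31.6%) were called, 2637 higher and 2959 lower in VCaP, and 734 were at least 4 log2 units apart; for 1552 the lower side and for 480 both sides were in the background range. Camera passed 7 of the 20 lists, and 3 passed with an estimated correlation. Androgen-responsive genes had 17 of 22 higher in VCaP, 1 lower and 4 not called (18 over the list alone), with a median of 3.64 (camera adjusted p = 4.96e-10; adjusted p = 0.0366 with an estimated correlation). Luminal genes had 15 of 23 higher, 4 lower and 4 not called (20 over the list alone; camera adjusted p = 0.000629; adjusted p = 0.384 with an estimated correlation). HOXB13, a homeobox factor of prostate, was at least 7.88 units higher in VCaP, and MUC1, a surface mucin, and KRT19 were at least 6.86 and 6.13 ± 0.25 (SE) lower. Mesenchymal genes had 17 of 27 lower, 3 higher and 7 not called (20 over the list alone; camera adjusted p = 1.2e-05; adjusted p = 0.0407 with an estimated correlation). Their median was -1.95 and, with members at their bounds, -0.0499. LGALS1 was at least 8.66 units lower in VCaP, and THBS1, thrombospondin, 3.79 ± 0.40 (SE) higher.

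Interferon response genes were lower in VCaP than in DU145 for 16 of 26 and higher for 0 (16 over the list alone; camera adjusted p = 2.19e-07; adjusted p = 0.0407 with an estimated correlation). IFIT3 and IFIT1, which bind viral RNA or act with the protein that does, were at least 3.98 and 2.86 log2 units lower. Genes of MHC class I presentation were lower for 11 of 14 and higher for 0 (11 over the list alone; camera adjusted p = 2.19e-07; adjusted p = 0.053 with an estimated correlation), with HLA-C and HLA-F at least 5.38 and 4.68 units lower and TAPBP, a peptide-loading factor, 1.93 ± 0.29 (SE). Neuroendocrine genes had 10 of 20 higher, 2 lower and 8 not called (12 over the list alone; camera adjusted p = 0.011; adjusted p = 0.241 with an estimated correlation). Their median was 0.997, and 0 with members at their bounds. CHGA and CHGB, the chromogranins, were at least 2.35 and 2.13 units higher in VCaP, and UCHL1 was 6.54 ± 0.23 (SE) lower. Cell cycle genes were lower for 13 of 30, higher for 1 and not called for 16 (14 over the list alone; camera adjusted p = 0.011; adjusted p = 0.616 with an estimated correlation). That list did not pass without DU145 replicate 1 (adjusted p = 0.171) or without VCaP replicate 1 (adjusted p = 0.12). BIRC5, the gene of survivin, was 2.16 ± 0.39 (SE) units lower in VCaP. Of 13 immune cell markers, 4 were lower in VCaP, 0 higher and 9 not called (camera adjusted p = 0.189). In the background range on all arrays were 8 of these 13. Of 12 endothelial and 13 fibroblast markers, 1 each was called, higher in VCaP (camera adjusted p = 0.778 and 0.333).

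The lists on bone did not pass between VCaP and DU145. Resorption factors had 1 of 20 higher and 5 lower (6 over the list alone; camera adjusted p = 0.217). CSF1, the growth factor of macrophages and osteoclasts, was at least 8.16 log2 units and DKK1 at least 5.35 lower in VCaP, and JAG1, a Notch ligand, at least 3.08 higher. Formation factors had 3 of 21 higher and 6 lower (9 over the list alone; adjusted p = 0.715), with BMP4 at least 4.63 lower and GDF15, a stress-induced cytokine, 4.04 ± 0.58 (SE) higher. Osteoblast-type genes had 2 of 18 higher and 1 lower (3 over the list alone; adjusted p = 0.291), and MGP was at least 4.80 higher in VCaP. The sterol list (10 of 24 higher, 3 lower, 15 over the list alone) had an adjusted p = 0.128, and 0.00348 without VCaP replicate 1. AKR1C1 and AKR1C2, near-identical steroid reductases that the array may not tell apart, were at least 6.01 and 4.19 units lower in VCaP. NR3C1, the glucocorticoid receptor, was 5.21 ± 0.37 (SE) lower and ZBTB16, a transcription factor that glucocorticoids induce, at least 4.05 higher, and that list (3 of 13 higher, 7 lower, 10 over the list alone) did not pass (adjusted p = 0.291). LMNA was 5.87 ± 0.24 (SE) units lower in VCaP and SATB1, a chromatin organiser, at least 1.74 higher, within a nuclear architecture list with 7 of 43 higher and 1 lower (8 over the list alone; adjusted p = 0.333).

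MDAPCa2a and MDAPCa2b, 2 lines of similar name from bone metastasis grown in the same medium, differed in far fewer genes. MDAPCa2a was at passages 14 and 15 and MDAPCa2b at passages 31 and 30, so effects of line and passage number cannot be separated here. MGST1, a membrane-bound glutathione transferase, was 5.51 ± 0.26 (SE) log2 units higher in MDAPCa2b (adjusted p = 3.48e-05). CYP4F8, a cytochrome of fatty acid metabolism, was at least 3.88 units higher (adjusted p = 3.77e-05), MSRA, which repairs oxidised methionine, at least 3.72 (adjusted p = 3.77e-05), and MAGEC1, a cancer-testis antigen, 3.99 ± 0.24 (SE, adjusted p = 8.24e-05). TSPAN12, a tetraspanin of Wnt signalling, was at least 5.57 lower in MDAPCa2b (adjusted p = 0.00038), and JAG1 was 4.22 ± 0.40 (SE) lower (adjusted p = 0.00126). BEX3 was at least 2.65 units higher, and TMTC1 and POTEJ at least 2.65 and 3.36 lower. POTEJ belongs to a family of near-identical copies and its identity is uncertain. POTEI was at 6.625 ± 1.02 in MDAPCa2b and 10.87 ± 0.147 in MDAPCa2a (SD, n = 2 each), and its call was lost without either MDAPCa2a array. CYP1B1 was at 11.2 ± 2.02 and 7.306 ± 0.0324 (SD, n = 2 each) and was not called on only the 4 arrays of these lines (limma adjusted p = 0.133).

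Of 17687 genes, 183 (1.03%) were called between MDAPCa2b and MDAPCa2a, 95 higher and 88 lower in MDAPCa2b, and 7 were at least 4 log2 units apart. This count depended on single arrays. It was 30 without MDAPCa2a replicate 1, 33 without MDAPCa2a replicate 2, 502 without MDAPCa2b replicate 1 and 108 without MDAPCa2b replicate 2; 152 of the 183 genes were among the 502. The balance of directions was as unsteady: 10 higher and 20 lower without MDAPCa2a replicate 1, 15 and 18 without replicate 2, 335 and 167 without MDAPCa2b replicate 1, 53 and 55 without replicate 2, and 79 and 92 with array medians set equal.

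Cell cycle genes were higher in MDAPCa2b, with 6 of 30 called over all genes, 0 lower, and 23 called when adjusted over the list alone. Their median difference was 1.61 log2 units (camera adjusted p = 4.11e-25). These genes vary together, and the call was lost with an estimated correlation (adjusted p = 0.429 with an estimated correlation) and with fry (adjusted p = 0.156). BUB1, a kinase of the spindle checkpoint, was 1.97 ± 0.32 (SE) units higher (adjusted p = 0.0209), but its adjusted p was 0.104 without MDAPCa2b replicate 2, 0.132 without MDAPCa2a replicate 1 and 0.274 without MDAPCa2a replicate 2. BIRC5, CDC20 and MCM5 were also called, 2.05, 1.64 and 1.62 log2 units higher in MDAPCa2b. Their calls were lost on only the 4 arrays of the MDAPCa lines (limma adjusted p = 0.0603, 0.0989 and 0.127). They were also lost without either MDAPCa2a array or either DU145 array. Camera also passed sterol genes, with 0 of 24 called, 4 over the list alone and a median of -0.305 (camera adjusted p = 0.0484, and 0.759 with an estimated correlation). Resorption factors had 0 of 20 higher, 1 lower (JAG1) and 1 over the list alone, with a median of -0.191, and 0 with members at their bounds. That list passed as well (camera adjusted p = 0.0484, and 0.429 with an estimated correlation). Both were lost without DU145 replicate 1 or 2 (adjusted p = 0.052), MDAPCa2a replicate 1 (0.0737) or MDAPCa2a replicate 2 (0.0648). Without MDAPCa2b replicate 1 the adjusted p was 0.136 for sterol genes and 0.0919 for resorption factors, and without MDAPCa2b replicate 2 it was 0.246 and 0.163. Nuclear architecture genes did not pass (adjusted p = 0.0581) but did without a VCaP array (0.0467) or MDAPCa2b replicate 1 (0.00612), and hypoxia genes passed without MDAPCa2b replicate 1 (0.00199). Lists with 1 called member had LMNB1, lamin B1, 2.76 ± 0.40 (SE) higher in MDAPCa2b, THBS1 2.56 ± 0.40 (SE), TRPM8, a cation channel, 1.78 ± 0.26 (SE) and CD44, a hyaluronan receptor, at least 1.32. Each of these 4 calls was lost when either MDAPCa2a array was left out, with adjusted p-values from 0.132 (LMNB1) to 0.226 (THBS1). Without MDAPCa2b replicate 2 the adjusted p was 0.0821 for LMNB1, 0.0658 for TRPM8 and 0.0843 for CD44.

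The 4 bone-derived lines were set against the 3 other lines, with the line as the replicate. PKP1, plakophilin-1 of desmosomes (chromosome 1), was at least 5.08 log2 units higher in the bone-derived lines (adjusted p = 0.0391), with levels from 10.73 to 12.12 in PC3, VCaP, MDAPCa2a and MDAPCa2b and from 5.87 to 6.24, in or near the background range, in LNCaP, 22RV1 and DU145. POF1B, an actin-binding protein, was lower in the bone-derived lines (adjusted p = 0.0391), but its level of 6.08 in the others lay near the background line and no size is given. These were the 2 genes called of 17687 (0.0113%), 1 higher and 1 lower, while 1117 had an unadjusted p under 0.05. MDAPCa2a and MDAPCa2b, the most alike pair of lines, count as 2 replicates here. With these lines averaged neither gene was called (adjusted p = 0.103 for PKP1 and 0.312 for POF1B), and with 22RV1 among the bone-derived lines both had an adjusted p = 0.959. Both calls were also lost when single lines were left out. The fitted difference of PKP1 moved little over the 7 leave-outs (4.93 to 5.39), so no single line was shown to carry its call. For POF1B, without a size, this was not judged. PKP1 was not called without LNCaP (adjusted p = 0.0855), 22RV1 (0.0926), DU145 (0.186), VCaP (0.126) or MDAPCa2a (0.188). POF1B was not called when any line was left out, with adjusted p-values from 0.0574 without PC3 to 0.358 without MDAPCa2b, and between these 0.0855 without LNCaP, 0.0926 without 22RV1, 0.137 without VCaP, 0.186 without DU145 and 0.188 without MDAPCa2a.

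The genes that came next by p did not pass. GRPR, the receptor of gastrin-releasing peptide, had a mean of 13.62 in the bone-derived lines and was at least 7.30 log2 units higher there (adjusted p = 0.152), and TRIB2, a pseudokinase, had a mean of 7.65 against the background range (adjusted p = 0.106). SLC23A2, a vitamin C transporter, was at 9.78 against 6.70 (adjusted p = 0.198), RALGAPB at 12.40 against 11.08 (adjusted p = 0.166), and ZNF785 was in the background range on both sides (adjusted p = 0.24). In the other direction, XAGE1B, a cancer-testis antigen with close copies, and DUSP23, a phosphatase, were at least 3.42 and 2.72 log2 units lower (adjusted p = 0.152 and 0.163). ZBTB41 was at 8.10 against 10.40 (adjusted p = 0.163), ALKBH6 at 7.33 against 9.27 (adjusted p = 0.152) and TTI2 at least 0.93 lower (adjusted p = 0.152).

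Camera passed 3 lists between bone-derived and other lines: cell cycle genes (median -1.16, adjusted p = 6.26e-08), androgen-responsive genes (median 1.21, adjusted p = 0.0225) and nuclear architecture genes (median -0.242, adjusted p = 0.0225). For cell cycle genes, only MDAPCa2a (-2.40 from the mean of lines) and MDAPCa2b (-0.695) lay below LNCaP (-0.133), while the bone-derived lines PC3 (0.573) and VCaP (0.214) lay above the mean. None of the 30, 22 and 43 members of these lists was called, over all genes or over the list alone. All 3 were lost with an estimated correlation (adjusted p = 0.778 with an estimated correlation for each) and with fry (adjusted p = 0.8). The androgen-responsive list did not pass without VCaP (0.106), MDAPCa2a (0.0941), MDAPCa2b (0.0642), 22RV1 (0.173) or DU145 (0.284), and the nuclear architecture list not without 22RV1 (0.297), PC3 (0.076), MDAPCa2a (0.0987) or MDAPCa2b (0.0642). Other lists passed only when a line was left out: sterol genes without LNCaP (0.0239), DU145 (0.0258) or VCaP (0.0198), ETS drivers without VCaP (0.0198), basal and MHC class I genes without DU145 (0.014 and 0.0055), and luminal and interferon genes without PC3 (0.00446 and 0.0364). MDAPCa2a and MDAPCa2b, alone grown in HPC1 medium, are both on the bone-derived side, so medium and origin are partly mixed in this comparison.

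22RV1 and LNCaP, 1 array each, were compared by value without a test. SPINK1, a trypsin inhibitor overexpressed in a subset of prostate cancers, was at least 8.82 log2 units higher in 22RV1, RGS2, a regulator of G-protein signalling, 8.91, HGF, a growth factor of epithelium, 8.20, ID1, an inhibitor of differentiation, 7.49 and TIMP1 7.10. SSX2B, a cancer-testis antigen with near-identical copies, was at least 9.95 higher. In LNCaP, TMPRSS2, a serine protease of prostate, was at least 8.50 units higher, SLC30A4, a zinc transporter, 8.49, LCP1, an actin-bundling protein, 7.73, TM4SF1 7.15, ACKR3, a chemokine receptor, 6.93 and RAB25 6.30. KLK3 was at 7.95 in 22RV1 and 15.91 in LNCaP, ABCC4, a transporter, at 6.38 and 13.96, and SLC45A3, prostein, at 7.80 and 13.41, whereas AKR1C3, an androgen-forming reductase, was at least 4.64 units higher in 22RV1.

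In all, 4038 genes were at least 1 log2 unit apart between these 2 arrays, 2101 higher and 1937 lower in 22RV1, and 331 at least 4, beside an SD between passages of 0.31 in the replicated lines. Among 10000 random lists matched on level, the median of androgen-responsive genes (-1.51) lay at percentile 0, that of luminal genes (-0.731) at 0.07 and that of hypoxia genes (-0.888) at 0.02. The medians of neuroendocrine (1.06), cell cycle (1.44), nuclear architecture (0.861) and sterol genes (1.15) lay at percentile 100. Most neuroendocrine genes were in the background range: 6 of 20 lay above the line in 22RV1 and 2 of 20 in LNCaP. Their median levels of 4.495 and 3.889 were below the background lines of 6.377 and 6.116, so the size of that difference is uncertain. These percentiles describe the 2 arrays and have no replicate check.

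The series is about the spatial compartments of chromosomes, so it was asked whether genes next to each other on a chromosome differed alike between lines. Over 17636 adjacent pairs, the correlation of log2 differences was 0.166 for VCaP against PC3, 0.175 for VCaP against DU145 and 0.0674 for MDAPCa2b against MDAPCa2a. The highest of 10000 shuffles of gene positions gave 0.0273, 0.0291 and 0.0352. In each of the 3 comparisons the one-sided permutation p was 1e-04, adjusted 1e-04, the smallest that 10000 shuffles can give. The first 2 comparisons share the VCaP arrays, and the correlations are across genes, which are not independent replicates. Without pairs of 1 gene family the correlations were 0.148, 0.145 and 0.0599. Neither compartments nor DNA copy number were measured here, so the likeness of neighbouring genes cannot be credited to either.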

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

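All tests in this part were chosen before their results were seen. In each of 32 sets of values of the 4 bone-derived lines, the value furthest from the others was judged by the ratio of its gap to the range (Dixon's test). The sets were the genes named in the bone comparison and the 20 gene lists. By chance alone, about 1 in 20 such sets would pass for 4 independent lines that do not differ, and 7 passed here, all of them lists. The genes were picked by their difference between these 4 lines and the others, which favours likeness among the 4, so that share does not apply to them. MDAPCa2a and MDAPCa2b were close to duplicates (correlation 0.990 between line means), so the share expected by chance is not known. The 7 sets are therefore not shown to be more than chance gives. They describe single lines among 4 and are not tests of a group.

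PC3 was the line that stood apart in 6 of the 7. Its median over mesenchymal genes was 10.03, against 4.86 in VCaP, 4.90 in MDAPCa2a and 4.89 in MDAPCa2b (ratio 0.991). For interferon response genes it was 7.86, against 4.73, 4.69 and 4.89 (ratio 0.937). Secreted factors that promote bone resorption had a median of 6.90 in PC3 and 3.94, 4.22 and 3.92 in the others (ratio 0.9), and those that promote bone formation 5.97 against 4.78, 4.62 and 4.62 (ratio 0.881). Basal epithelium genes were at 8.06 in PC3 and at 5.68, 5.38 and 5.50 in the others (ratio 0.885). Androgen-responsive genes were lowest in PC3, at 7.67 against 13.22, 12.96 and 12.29 (ratio 0.833). PC3 had only 1 array, so none of these values has a replicate, and the medians near 4 or 5 lie in the background range. The PC3 median of bone formation factors (5.97) was also below the background line of its array (6.484). All 4 medians of that set thus lie in the background range, and they do not show that PC3 stands apart there.

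Immune cell markers were lowest in VCaP, with a median of 3.68 against 4.60 in PC3, 4.63 in MDAPCa2a and 4.53 in MDAPCa2b (ratio 0.891). All 4 of these medians lie in the background range, so they say nothing about immune cells.

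The comparison of bone-derived with other lines was repeated for all 35 ways to split the 7 lines into 4 and 3. At least 2 genes, the number found for the bone-derived lines, were called in 6 of the 35 splits, the real one among them. The highest count was 53, for LNCaP, VCaP, MDAPCa2a and MDAPCa2b against 22RV1, DU145 and PC3. It is the largest picked from the 35 splits, and whether it reflects a structure of the samples was not tested. At least 3 gene lists passed in 24 of the 35 splits, with up to 10 in another split. Neither the 2 genes nor the 3 lists of the bone comparison can be told apart from chance.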

How the results depend on the processing

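No paired analysis was possible because the labels name no culture, subject or processing unit that the groups compared share; they give only a replicate number, and it runs with the passages in 3 lines and against them in MDAPCa2b. Where no reason is given below, the cause was not tested. The leave-outs of gene lists were chosen after the first results were seen. No named gene that was called and no list that passed in the fit on all arrays changed its direction. The directions of the other called genes were not checked one by one. Among the other lists, endothelial markers for VCaP against PC3 were down by camera and up by fry (adjusted p = 0.00085), osteoblast-type genes up and down (fry adjusted p = 0.174), and interferon genes in the bone comparison up and, without PC3, down (adjusted p = 0.0364).

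The stricter minimum of 2 log2 units left 6531 genes that differed among lines, 2401 for VCaP against PC3, 2528 for VCaP against DU145 and 80 for MDAPCa2b against MDAPCa2a, lower by construction. Other scalings, a different choice of features, a filter on dim genes and another variance prior kept these 4 counts within 1.5-fold. Without 1 array, the genes that differed among lines numbered 9280 to 10351, those of VCaP against PC3 4703 to 5284 and those of VCaP against DU145 5353 to 5619. For MDAPCa2b against MDAPCa2a, leave-outs gave 30 (without MDAPCa2a replicate 1) to 502 (without MDAPCa2b replicate 1), and the fit on only its 4 arrays gave 100.

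The bone comparison called 2 genes on all 7 lines, 1 among genes above the median level and 10 with the 11 arrays and the line as a random block. It called 0 with MDAPCa2a and MDAPCa2b averaged (limma; 729 genes at an unadjusted p under 0.05). Leaving out a line gave from 0 (without DU145; limma; 1196 genes at an unadjusted p under 0.05) to 5 (without LNCaP). Without 22RV1, and with 22RV1 among the bone-derived lines, 2 genes were called, of which 0 were shared with the 2 reported.

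Of 20 lists, the estimated correlation left 3 for VCaP against PC3, 3 for VCaP against DU145, 0 for MDAPCa2b against MDAPCa2a (camera; 2 at an unadjusted p under 0.05) and 0 for the bone comparison (camera; 0 at an unadjusted p under 0.05). Fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, passed 16, 16, 0 and 0, with 16, 16, 3 and 1 at an unadjusted p under 0.05. Without 1 array, 10 to 12 lists passed for VCaP against PC3, 6 to 7 for VCaP against DU145 and 1 (without DU145 replicate 1) to 4 (without VCaP replicate 1) for MDAPCa2b against MDAPCa2a. Without 1 line, 1 (without 22RV1) to 5 (without DU145) passed for the bone comparison.

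On the 1000 genes with the largest SD, the lowest correlation within a line was 0.979 and the highest between lines 0.972. Among the settings for single named genes, 1318 of 1356 kept their call for VCaP against PC3, 1268 of 1308 for VCaP against DU145, and 286 of 340 for MDAPCa2b against MDAPCa2a. The bone comparison had only 2 called genes, PKP1 and POF1B, whose losses account for all 18 of its weaker settings.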

Other observations

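The tests below of the MDAPCa lines left out, of copy number read on genes above background, of a loss of signal by level, of admixture at a needed share, and the form of the test of a shift of all genes were chosen after the results were seen. The patterns themselves were noticed in the data.

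Several genes were the property of 1 line. With the other lines taken at no less than their background line, 43 genes in DU145, 28 in PC3, 25 in VCaP, 24 in 22RV1, 8 in LNCaP and 0 in MDAPCa2a and MDAPCa2b were at least 4 log2 units above every other line. LMO3 (16.14) led in DU145, with FAM83A, an oncogenic kinase adaptor, at 14.69. MSMP (17.19) led in PC3, with FST, the activin antagonist follistatin, at 13.50. In VCaP, ERG led, with ITM2A, a membrane protein of muscle and cartilage differentiation, at 15.76 and NPY at 15.51. In 22RV1, SPINK1 was at 14.94, HSPB6, a small heat shock protein, at 13.39 and PTPRB, a phosphatase of blood vessels, at 12.78. ACKR3 was at 13.31 in LNCaP and ADAMTS1, a matrix protease, at 13.29. A gene high in both MDAPCa2a and MDAPCa2b, which are alike, could not enter these counts. Whether this accounts for their counts of 0 was not tested.

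Genes of the short-arm side of chromosome 8 tended to be lower in the bone-derived lines. Of 227 genes, 151 were lower, with a median difference of -0.398 log2 units (95% bootstrap interval over genes -0.491 to -0.193), the most significant of 42 chromosome sides scanned (camera adjusted p = 7.87e-08; adjusted p = 0.00495 with an estimated correlation). The medians from the mean of lines were 0.0851 in LNCaP, 0.147 in 22RV1 and 0.0452 in DU145, and -0.116, -0.137, -0.13 and -0.141 in PC3, VCaP, MDAPCa2a and MDAPCa2b. POLR3D, a subunit of RNA polymerase III, was at 8.41 against 9.86 and VPS37A, an endosomal sorting protein, at 7.46 against 9.68, and neither passed alone (adjusted p = 0.198 and 0.265).

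For this arm, only 1 of the 35 splits, the real one, gave so large a median (highest other 0.244), but in 9 of the 35 some arm shifted as much (up to 0.625): the real one and 8 led by the short-arm side of chromosome 18, with only 63 genes, so a chance find from the search cannot be excluded. Dim features were not the source: the median of the 142 genes above background was -0.868 (-1.19 to -0.665), and without MDAPCa2a and MDAPCa2b that of all genes was -0.317 (-0.516 to -0.148). A lower copy number of the whole arm should lower all 3 parts of it, and on all genes the least shifted part had -0.177 (-0.412 to 0.0261), which met the bound written beforehand against that reading. That bound was set aside after it was seen, because only 34 of the 76 genes of that part were above background; on genes above background the least shifted part had -0.678 (-0.868 to -0.478), as a lower copy number would give. Copy number may thus be a reason, but the rule that favours it came after the result, the interval treats neighbouring genes as independent, and DNA was not measured.

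MDAPCa2b replicate 2, the earlier passage (30), differed from replicate 1 (passage 31) in dividing-cell genes. Cell cycle genes were higher by a median of 0.66 log2 units (95% bootstrap interval 0.27 to 0.992), 10 of 30 by at least 1 and 1 lower by as much, above all of 10000 random lists. Their medians were 9.55 and 10.00 in MDAPCa2b and 8.30 and 8.02 in MDAPCa2a. TFF1, a trefoil factor that estrogen and androgen signals can alter, was at 5.19 in replicate 1 and 9.95 in replicate 2, and CDC45, a replication factor, at 6.86 and 9.99. EGR1 and FOS, immediate early genes, were at 12.68 and 10.10 in replicate 1, 5.82 and 6.56 in replicate 2, and 14.15 and 11.95 in MDAPCa2a. Sterol gene medians were 9.50 and 8.63 in MDAPCa2b and 10.18 and 10.39 in MDAPCa2a.

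The area under the control curve was 0.981 in replicate 2, within 0.977 to 0.985 on the other arrays, but replicate 1 was itself the lowest of the 11 (0.977), so a weak replicate 1 stays open. The list stood 0.662 (0.234 to 1.01) above the median of genes of the same level and 0.689 (0.299 to 1.02) above the median of all genes. The rise was thus one relative to other genes. Because RMA brings all arrays to the same distribution, these medians of other genes were bound to lie near 0. The tests therefore cannot exclude a loss that depends only on a gene's level, or a shift shared by all genes, before that step. The intervals also treat genes that vary together as independent. Admixture of another line was open by the first test: genes high in LNCaP and in the background range here differed by a median of 0.237 (-0.287 to 2.09, 9 genes), too wide to decide, while the 4 other lines had upper bounds under 1. At the share of another line that the cell cycle genes would need, genes of that line should have been far higher than measured, by 5.88 log2 units or more for the nearest line, 22RV1 (measured minus predicted -5.88, -7.04 to -5.03). No cause in the culture was tested, and with 1 array per passage growth state and handling at harvest cannot be separated.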
